A study of Mus musculus with 6 samples.

How the data were processed

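The study holds 6 stranded mRNA libraries of C57B/6 mouse knee cartilage chondrocytes, 3 from cells given vesicles of unstimulated macrophages (M-EV) and 3 from cells given vesicles of LPS-stimulated macrophages (M-LPS-EV). Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, STAR, RSEM and DESeq2 were used with the mm10 genome build; their versions, settings, read trimming, strand setting and annotation are not given in the sources used here. STAR aligns reads and RSEM shares reads that fit several transcripts between them by maximum likelihood.

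Each deposited file is a table of transcripts for 1 library. The authors deposited an expected count per transcript, which RSEM estimates and which need not be a whole number. The TPM column deposited beside it is scaled by effective transcript length, per the file headers. The deposited IsoPct column gives each transcript's percent of its gene's abundance, per the file headers, and length columns in the deposited tables give transcript and effective length in bases. All files hold the same 142699 transcripts of 55487 genes. Of the transcript identifiers 99.14% were also in GENCODE M21, whose build is GRCm38 (mm10), and 99.7% of the shared transcripts had the same length there, so coordinates and gene types were taken from that annotation, 1-based. Symbols were found for 55141 genes. The other 346, with 0.0130% to 0.0142% of the counts, kept their identifiers and stayed in the counts.

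Expected counts were summed over the transcripts of each gene and rounded to whole numbers. Genes were filtered with edgeR's filterByExpr at its defaults (minimum count 10, minimum total 15), which left 14604 genes with 99.9% of the counts, library sizes were scaled by TMM, and a quasi-likelihood model with group as the only term was fitted (edgeR 4.0.16, glmQLFit and glmQLFTest, R 4.3.3). A gene was called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over all tested genes; tests were two-sided. Fold changes are M-LPS-EV over M-EV, CPM are counts scaled to a common total with TMM-scaled library sizes, and SD are over the 3 libraries of a group. Where a size is given for a gene with 0 counts in a group, it is a bound against 3 counts over that group. For one with 1 to 3 counts it is a ratio with its exact conditional 95% interval. Both cover counting error only. Gene lists fixed before the data were examined, 27 in number, were tested with camera in limma 3.58.1 on voom values, with an inter-gene correlation preset at 0.01, where at least 3 members were tested (24 lists), with Benjamini-Hochberg adjustment over the lists. Transcript usage was tested with edgeR's diffSpliceDGE on quasi-likelihood fits of rounded transcript counts, for genes with at least 2 transcripts passing filterByExpr, with Simes p-values per gene. RSEM's uncertainty in sharing reads between transcripts and between near-identical genes is not modelled, so p-values for such transcripts and genes may be too small.

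The tests were tried on simulated counts with the means and depths of these libraries. For M-LPS-EV against M-EV, with 14413 genes in the step, the gene test recovered 16 of 47 tested genes changed by 0.25 on the log2 scale, 41 of 50 changed by 0.5, 44 of 49 changed by 1 and 50 of 50 changed by 2, and 5 of 14217 unchanged genes were called. The list test called the 1 list that was moved and 0 of 5 that were not. The simulated genes varied independently of each other, so this does not show how the list test behaves when members of a list are correlated. The usage test, with 8232 genes in the step, called 6 of 100 genes in which a second transcript was changed by 1 on the log2 scale and 42 of 100 changed by 2, but also 48 unchanged genes, so its error rate was not held; with only transcripts of at least 10% of their gene, 5222 genes in the step, it called 43 changed and 9 unchanged genes.

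The naming rule, fixed before the data were examined, took the 12 highest and 12 lowest log2 fold changes among called genes with a mean CPM of at least 1 and non-overlapping groups, leaving out unnamed gene models; up to 4 members of each list with the smallest p; 15 genes of pyroptosis, inflammation and cartilage whatever their values (Casp4, Casp1, Gsdmd, Nlrp3, Il1b, Il6, Tnf, Mmp3, Mmp13, Adamts4, Adamts5, Col2a1, Acan, Sox9 and Tlr4); and the 6 genes with the smallest adjusted p for usage. The text gives fewer of these. The alternatives chosen in advance were RLE and upper-quartile scaling, no count filter, a mean count of at least 50, effective length offsets, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), a minimum log2 fold change of 1, camera with an estimated correlation, fry, and for usage a mean count of at least 50, the gene-level F-test, only transcripts with at least 10% of their gene's TPM, the block and each library left out. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.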

Results

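RNA of cultured mouse knee cartilage chondrocytes, the cells that make and maintain cartilage matrix, was measured by sequencing of stranded mRNA libraries. The cells had received extracellular vesicles, small membrane particles that cells release, at 10 µg/ml of vesicle protein for 24 h. In 3 libraries the vesicles came from unstimulated macrophages (M-EV) and in 3 from macrophages stimulated with LPS, a bacterial cell wall component (M-LPS-EV). The design holds 1 comparison, M-LPS-EV against M-EV. Cells that received no vesicles were not analysed here. Each value is thus a difference between the vesicle types and not a response to vesicles as such. The series title names the question: whether vesicles of inflammatory macrophages start the non-canonical route of pyroptosis, a lytic cell death, in chondrocytes and lead to breakdown of cartilage as in osteoarthritis.

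The expected counts summed to 25712667, 22274687 and 22730480 in the M-EV libraries and to 21159254, 23539911 and 20239626 in the M-LPS-EV libraries. Col2a1, the gene of the main cartilage collagen, held 8.48% to 8.61% of all counts with M-EV and 7.63% to 7.80% with M-LPS-EV. Libraries of 1 group differed from each other by more than sampling noise, with a mean chi-square per degree of freedom between 1.69 and 2.79. Between groups that value lay between 26.7 and 33.8, and the first principal component, with 60.4% of the variance, separated the groups. The labels do not say that the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

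Chondrocytes that received M-LPS-EV had higher levels of most tested chemokine genes and of all tested NF-kB response genes. They also had higher levels of the matrix proteases Mmp3 and Mmp13 and of the pyroptosis genes Casp4 and Gsdmd, and lower levels of most cartilage matrix genes. Saa3, an acute-phase protein, rose from 1.38 ± 0.111 to 315 ± 17.4 CPM (mean ± SD, n = 3 per group). Lcn2, an iron-sequestering protein of innate defence, rose from 48.3 ± 1.87 to 1171 ± 42.5 CPM and Mmp3 from 3.27 ± 0.320 to 235 ± 22.4 CPM. Among the cartilage genes Matn1, a matrix adaptor protein, fell from 2522 ± 7.74 to 1354 ± 12.1 CPM and Acan, the main cartilage proteoglycan, from 10811 ± 11.2 to 8257 ± 95.1 CPM. Of 14604 genes tested, 4614 were called (adjusted p under 0.05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided), 2397 higher and 2217 lower with M-LPS-EV. Large changes went mainly up: 311 genes rose and 84 fell by at least 1 on the log2 scale, and 96 rose and 8 fell by at least 2. Sizes given with an SE are log2 fold changes of M-LPS-EV over M-EV. Of all calls, 2358 were under 1.2-fold. With each library's effective transcript lengths as an offset 2868 genes were called, and limma-trend on log2(TPM + 1) called 2622. A test against a change of at least 1.2-fold, chosen after the data were seen, left 1137 genes with changed expression and not Col2a1, Timp3, Ninj1, Nek7, Ddit3 or Insig1. The groups did not overlap for 42.2% of the tested genes, against 10.0% by chance for 3 against 3.

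**Figure D1:**
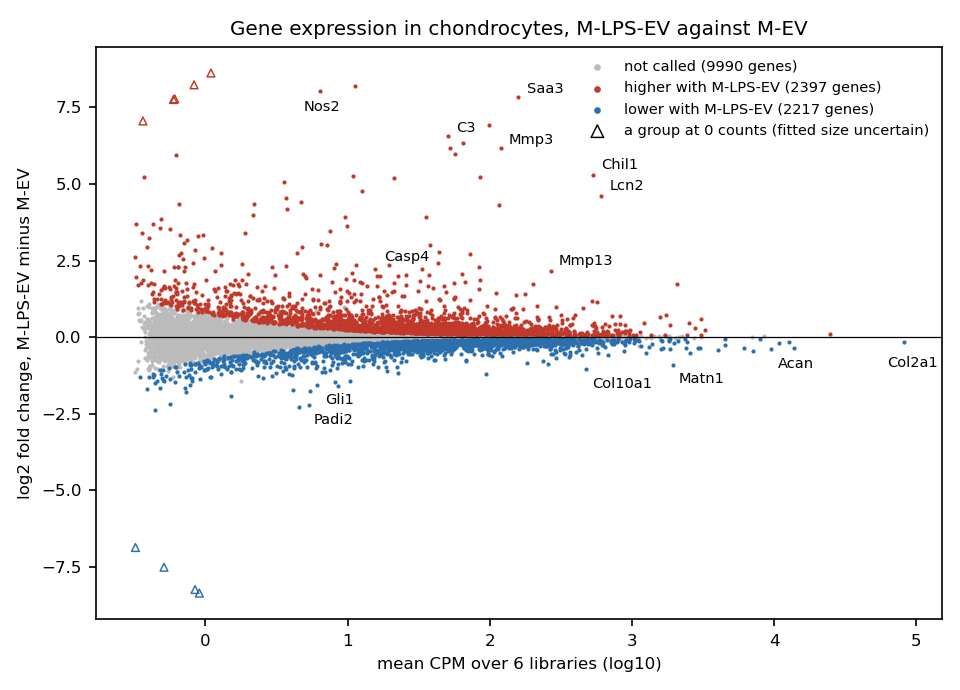
Log2 fold change (M-LPS-EV minus M-EV, vertical axis) against the mean CPM over the 6 libraries (log10, horizontal axis), 1 mark per tested gene, red for the 2397 genes called higher, blue for the 2217 called lower and gray for the others; triangles are genes at 0 counts in a group, whose fitted size is uncertain. Large changes lie mainly upward, for example at Saa3, C3 and Mmp3, while abundant cartilage genes such as Acan and Col2a1 lie slightly below 0.

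The 12 genes with the highest log2 fold changes under the fixed naming rule were Saa2, Vnn3, Nos2, Saa3, Steap4, C3, Hp, Cxcl1, Mmp3, Cxcl5, Chil1 and Cfb. Nos2, the inducible nitric oxide synthase, went from 3 counts in the 3 M-EV libraries to 840 in the M-LPS-EV libraries, a ratio of 300.1 (95% counting interval 102 to 1458). Saa2 had 0 and 142 counts and was at least 50.7-fold higher, against a floor of 3 counts over the group. It shares sequence with its neighbour Saa1, so the split of reads between them is uncertain. Steap4, a metalloreductase, rose from 1.59 ± 0.166 to 195 ± 7.95 CPM, and Hp, which encodes the haemoglobin-binding haptoglobin, from 1.61 ± 0.204 to 129 ± 7.49 CPM. Chil1, a chitinase-like secreted protein of cartilage and macrophages, reached 1040 ± 58.8 CPM from 26.6 ± 1.37 CPM (log2 fold change 5.29, SE 0.04, edgeR adjusted p = 4.2e-32). In the list of TLR4 and NF-kB response genes all 28 tested members rose, 21 of them by at least 1 on the log2 scale, with a median log2 fold change of 1.496 (camera adjusted p = 9.6e-34). Examples besides Lcn2 and Saa3 were Nfkbiz, an inducible NF-kB cofactor, with a log2 fold change of 3.02 (SE 0.05), and Icam1, a leukocyte adhesion molecule, with 2.43 (SE 0.05). Tlr4, the LPS receptor itself, rose by 0.46 (SE 0.07), from 17.7 ± 1.51 to 24.3 ± 2.24 CPM, a call that ended with effective length offsets (0.27, edgeR adjusted p = 0.19) and on the TPM scale (0.23, limma adjusted p = 0.29). Of 15 tested chemokine genes (of 25 in the list) 13 rose and none fell (median log2 fold change 3.70, camera adjusted p = 2.4e-13). The neutrophil attractants Cxcl1 and Cxcl5 rose by 6.19 (SE 0.07) and 5.98 (SE 0.07), and the monocyte attractants Ccl2 and Ccl7 by 5.18 (SE 0.11) and 4.77 (SE 0.12). Among 13 tested cytokine and growth factor genes (of 25) 8 rose and none fell, with 8 up and 2 down when adjusted over the list alone. The list passed camera (adjusted p = 0.0022) but not with an estimated correlation (camera adjusted p = 0.14). Ereg, an epidermal growth factor family ligand, rose from 1.08 ± 0.321 to 8.52 ± 0.341 CPM. Il6 went from 1 to 80 counts per group, a ratio of 85.8 (95% counting interval 14.96 to 3429). Genes near 0 with M-EV, such as Nos2 and Il6, reached the test only through their M-LPS-EV counts. Once tested they could only rise, which can lift a list's number of risers and its median. Il1b had 0 and 9 counts and Tnf 3 and 18 counts in the M-EV and M-LPS-EV groups, too few for the test. By counts alone Il1b was at least 3.2-fold higher, against a floor of 3 counts over the group. The ratio of Tnf was 6.4 (95% counting interval 1.88 to 34.1).

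In the list of inflammasome and pyroptosis genes 11 of 23 members had enough counts for the test; 4 rose, 1 fell and 6 were not called. Casp4 (ENSMUSG00000033538), on chromosome 9 from 5308828 to 5336783 in mm10, encodes the caspase that binds intracellular LPS in the non-canonical route. It rose from 5.49 ± 0.822 to 25.9 ± 0.640 CPM (log2 fold change 2.23, SE 0.08, edgeR adjusted p = 4.2e-17). Gsdmd (ENSMUSG00000022575), on chromosome 15 from 75862327 to 75867408, encodes gasdermin D, the pore-forming protein that this caspase cleaves. It rose from 0.600 ± 0.262 to 1.75 ± 0.165 CPM, or from 43 to 114 counts per group (log2 fold change 1.51, SE 0.29, edgeR adjusted p = 0.00022). Ninj1, which acts in plasma membrane rupture, rose by 0.31 (SE 0.03), and Nek7, a partner of the NLRP3 inflammasome, fell by 0.18 on the log2 scale (SE 0.04), but not past the threshold on the TPM scale (limma adjusted p = 0.062). Il18, a cytokine that caspase-1 matures, was the other member called higher (0.61, SE 0.16, edgeR adjusted p = 0.0049) and is named after its values were seen. Of the canonical route, Casp1 had 6 and 3 counts and Nlrp3 6 and 16 counts in the M-EV and M-LPS-EV groups, near the detection limit. Their count ratios were 0.54 (95% counting interval 0.087 to 2.51) and 2.86 (1.06 to 8.92). The adaptor Pycard, also named after its values were seen, was tested with 69 and 89 counts and not called. The list passed camera (adjusted p = 0.014) and lost its call with an estimated correlation (camera adjusted p = 0.14). Of 16 tested genes of apoptosis and necroptosis 8 rose and none fell (camera adjusted p = 0.00014). The death receptor Fas rose from 3.78 ± 0.569 to 19.0 ± 0.792 CPM (log2 fold change 2.34, SE 0.10) and Bid, which links death receptors to mitochondria, by 1.49 (SE 0.10). Ripk3, a necroptosis kinase, rose by 0.44 (SE 0.08), a call that ended with the length offset (0.31, edgeR adjusted p = 0.12) and on the TPM scale (0.28, limma adjusted p = 0.16). Transcript levels do not show cleavage of a caspase or of gasdermin D, nor cell death.

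Cartilage matrix and chondrocyte identity genes fell as a group. Of 26 tested members 16 fell, 4 rose and 6 were not called, with a median log2 fold change of -0.26 (camera adjusted p = 1.2e-11); adjusted over the list alone 16 fell and 5 rose. The falls were small beside the inflammatory changes. Matn1 had a log2 fold change of -0.90 (SE 0.02, edgeR adjusted p = 4.2e-24). Col11a2 and Col11a1, chains of a fibril-nucleating cartilage collagen, had -0.45 (SE 0.02) and -0.34 (SE 0.01). Those of Acan and Col2a1 were -0.39 (SE 0.01) and -0.17 (SE 0.01). The transcription factors Sox5 and Sox6 of the list, named after their values were seen, had 0.03 and -0.002. They were not called (edgeR adjusted p = 0.58 and 0.97). Sox9, the main transcription factor of chondrocytes, had a log2 fold change of 0.06 (SE 0.03) and was not called (edgeR adjusted p = 0.097). It was called without M-EV replicate 1 (0.08, edgeR adjusted p = 0.0495), without M-LPS-EV replicate 1 (0.08, adjusted p = 0.043) and with a GC content and length offset chosen after the data were seen (0.07, adjusted p = 0.047). Genes of chondrocyte hypertrophy split: 3 of 10 rose and 6 fell, and the list was not called (camera adjusted p = 0.11). Col10a1, the collagen of hypertrophic chondrocytes, fell from 636 ± 3.45 to 308 ± 6.19 CPM, and Panx3, a channel protein, fell by 0.45 on the log2 scale (SE 0.03). Spp1, which encodes osteopontin, rose by 1.16 (SE 0.03) and the angiogenic factor Vegfa by 0.50 (SE 0.03).

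Among 19 tested matrix-degrading enzymes 8 rose, 2 fell and 9 were not called. The stromelysin Mmp3 (ENSMUSG00000043613), on chromosome 9 from 7445822 to 7455975, rose by 6.18 on the log2 scale (SE 0.08, edgeR adjusted p = 2.0e-27) and the collagenase Mmp13 (ENSMUSG00000050578), on chromosome 9 from 7272514 to 7283331, from 98.2 ± 1.97 to 439 ± 11.8 CPM (log2 fold change 2.16, SE 0.03, edgeR adjusted p = 1.0e-27). The aggrecanase Adamts5 rose from 6.49 ± 0.396 to 10.4 ± 1.17 CPM (log2 fold change 0.69, SE 0.10), while Adamts4, the other main aggrecanase, stood at 1.21 ± 0.315 and 1.22 ± 0.0777 CPM (log2 fold change 0.02, SE 0.27, edgeR adjusted p = 0.97) and was not called. Its sign turned under some alternatives, to -0.18 without M-EV replicate 3 and -0.04 without M-LPS-EV replicate 1. The list passed camera (adjusted p = 0.0016) but not with an estimated correlation (camera adjusted p = 0.070). Of 9 tested protease inhibitors 6 rose and 2 fell (camera adjusted p = 0.0022), a call that was also lost (adjusted p = 0.058 with an estimated correlation). Serpina3n, a secreted serine protease inhibitor, rose by 1.66 (SE 0.04), and Timp3, an inhibitor of metalloproteinases and aggrecanases, fell by 0.25 on the log2 scale (SE 0.02).

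**Figure D2:**
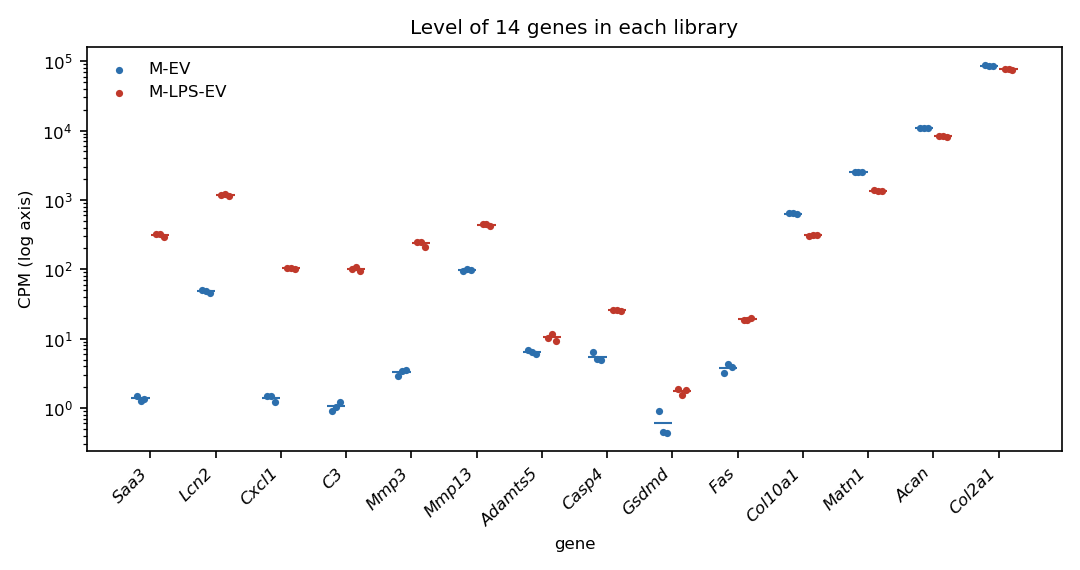
CPM on TMM-scaled library sizes (vertical log axis) of 14 genes (horizontal axis) in the 3 M-EV libraries (blue) and the 3 M-LPS-EV libraries (red), 1 point per library with a bar at the group mean. For each gene every library of 1 group lies above every library of the other, upward for Mmp3 (3.27 to 235 CPM on average) and Casp4 (5.49 to 25.9 CPM) and downward for Matn1 and Acan.

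Genes downstream of interferons moved unevenly. Interferon-inducible GTPases attack membranes of intracellular microbes and pathogen vacuoles. Of 8 tested (of 18) 7 rose and none fell, with a median log2 fold change of 1.80 (camera adjusted p = 4.0e-05). Adjusted over the list alone 8 rose. Members near 0 with M-EV, such as Gbp5 with 4 counts there and 59 with M-LPS-EV, reached the test only through M-LPS-EV. Gbp6 rose from 0.404 ± 0.0193 to 8.96 ± 1.38 CPM and Gbp2 from 0.396 ± 0.208 to 7.11 ± 0.659 CPM. Members of this family share sequence, so the split between them is uncertain. In the list of antiviral interferon-stimulated genes only 20 of 36 members could be tested, of which 9 rose, 2 fell and 9 were not called. Adjusted over the list alone 10 rose and 2 fell. Cmpk2, a mitochondrial nucleotide kinase, rose from 15 to 70 counts per group (log2 fold change 2.30, SE 0.44; limma adjusted p = 0.051 on the TPM scale), and Bst2, which tethers budding viruses to the cell surface, by 0.65 (SE 0.14). The list's camera call (adjusted p = 0.031) was lost with an estimated correlation (camera adjusted p = 0.11). It was lost too without M-EV replicate 3 (camera adjusted p = 0.072), without M-LPS-EV replicate 1 (0.057) and with a mean count of at least 50 (0.056). MHC class I presentation genes rose together, 14 of 17 with none lower (median log2 fold change 0.73, camera adjusted p = 4.5e-13). Tapbp, which loads peptides onto MHC class I molecules, rose from 42.8 ± 2.16 to 126 ± 4.72 CPM and H2-K1, a class I heavy chain, by 0.89 (SE 0.04). Of 12 tested complement genes 8 rose and 1 fell (camera adjusted p = 2.3e-06). C3, the central complement protein, rose from 1.06 ± 0.170 to 101 ± 6.33 CPM. Cfb, a protease of the alternative pathway, rose from 0.548 ± 0.162 to 21.5 ± 0.486 CPM and the classical pathway proteases C1s1 and C1ra by 2.79 (SE 0.05) and 1.87 (SE 0.05).

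Most genes of glycolysis and proliferation rose, and most of the unfolded protein response fell. All 18 genes of glycolysis and hypoxia rose (median log2 fold change 0.64, camera adjusted p = 8.7e-33). Among them were the glycolytic enzymes Pkm (0.73, SE 0.02) and Tpi1 (0.67, SE 0.02), the lactate exporter Slc16a3 (1.03, SE 0.03) and the hypoxia-induced carbonic anhydrase Car9 (1.76, SE 0.05). Of 26 proliferation genes 21 rose and 1 fell, with 23 up and 1 down when adjusted over the list alone (median 0.28, camera adjusted p = 1.2e-13). Mki67, a marker of cycling cells, rose from 316 ± 7.71 to 414 ± 9.32 CPM and the mitotic checkpoint gene Bub1b by 0.47 (SE 0.04). In the list of NRF2 targets and metallothioneins 8 of 15 genes rose and 1 fell, with 9 up and 1 down when adjusted over the list alone (camera adjusted p = 0.00014). The largest rises there were of the metal-binding metallothioneins Mt2 (1.72, SE 0.04) and Mt1 (1.40, SE 0.04), and Slc7a11, the cystine transporter, rose by 0.64 (SE 0.05). Of 16 genes of the unfolded protein and integrated stress response 13 fell and none rose (median -0.19, camera adjusted p = 8.5e-09). The endoplasmic reticulum chaperone Hspa5 fell from 1841 ± 12.7 to 1452 ± 19.0 CPM and the stress gene Ddit3 by 0.25 on the log2 scale (SE 0.03). Among 19 cholesterol synthesis genes 9 fell and none rose (camera adjusted p = 0.00028), a call lost with an estimated correlation (camera adjusted p = 0.11). Insig1, a sterol sensor partner, fell by 0.25 (SE 0.04) on the log2 scale. Of 14 immediate-early and heat-shock genes 7 rose and 1 fell (camera adjusted p = 0.0057), a call again lost with an estimated correlation (camera adjusted p = 0.11). Ier3 rose by 2.29 (SE 0.04), Junb by 1.61 (SE 0.05), and the heat-shock gene Hsph1 fell by 0.35 (SE 0.03) on the log2 scale.

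Markers of other cell types were mostly low, apart from fibroblast markers. With M-EV and M-LPS-EV, Dcn stood at 456 and 629 CPM and Col1a2 at 632 and 497 CPM, and only 7 of 16 fibroblast markers were not called. The counts of called markers stand beside the 31.6% called among all tested genes. Of 12 tested macrophage markers (of 22) 5 were called higher and none lower (camera adjusted p = 0.038), which stands beside the rise of the NF-kB, chemokine, complement and MHC lists. Among the 10 members with too few counts for the test were C1qa, with 37 and 2 counts in the M-EV and M-LPS-EV groups, C1qb, with 34 and 5, and C1qc, with 14 and 2. These complement C1q genes were chosen after their values were seen, and their counts were lower with M-LPS-EV. The call of the list was lost with an estimated correlation (camera adjusted p = 0.12), with the length offset (0.17), without a count filter (0.38) and with a mean count of at least 50 (0.32). It was also lost without M-EV replicate 1 (0.15), M-EV replicate 3 (0.084) or M-LPS-EV replicate 1 (0.20), 2 (0.13) or 3 (0.33). Lyz2, a lysozyme, went from 15.5 ± 0.823 to 22.2 ± 2.06 CPM and Adgre1, a surface receptor of macrophages, from 0.735 ± 0.163 to 2.11 ± 0.223 CPM. Cybb, an oxidase subunit of phagocytes, went from 19 to 109 counts per group (log2 fold change 2.59, SE 0.40). Its M-EV level was 0.078, 0.181 and 0.576 CPM in replicates 1, 2 and 3, so the size leans on replicate 3. The call of Cybb ended with the length offset (1.88, edgeR adjusted p = 0.21) and on the TPM scale (0.22, limma adjusted p = 0.72), where the added 1 shrinks sizes. Of 16 fibroblast markers 4 rose and 5 fell, with 5 and 5 when adjusted over the list alone (median 0.06 but mean -0.04, camera adjusted p = 0.86). Dcn, a small proteoglycan also made by chondrocytes, rose by 0.46 (SE 0.02) and Col1a2, a type I collagen chain, fell by 0.35 (SE 0.02) on the log2 scale. Of 6 osteoblast markers 1 rose and 1 fell, with 1 up and 2 down when adjusted over the list alone (camera adjusted p = 0.36). None of 3 endothelial (median -0.04 but mean 0.11, camera adjusted p = 0.82) and 8 skeletal muscle markers (0.85) was called. Of 2 tested osteoclast markers 1 rose, of 2 adipocyte markers 1 rose and 1 fell, and no erythroid marker had enough counts. In every list for which no such count is given, adjustment over the list alone gave the same counts as adjustment over all genes.

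**Figure D3:**
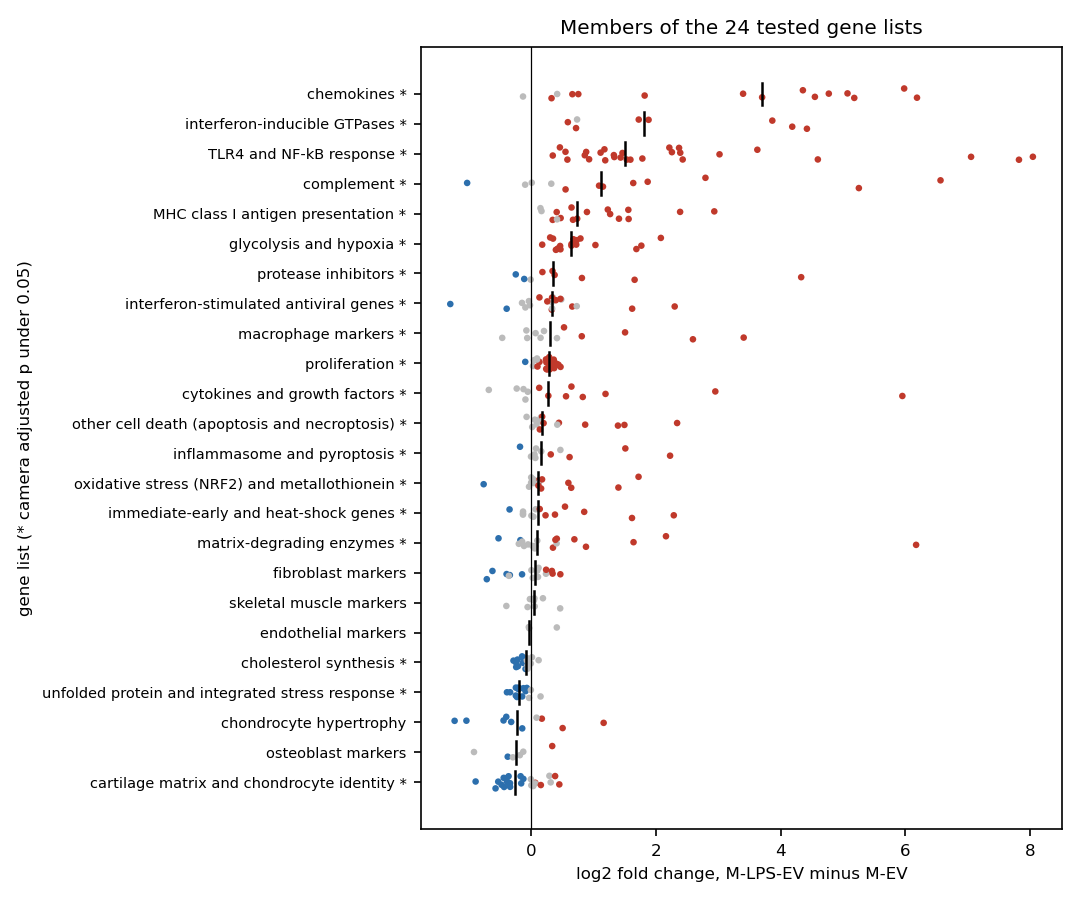
Log2 fold change (M-LPS-EV minus M-EV, horizontal axis) of each tested member of the 24 gene lists (vertical axis, sorted by median), red for genes called higher, blue for genes called lower and gray for the rest, with a black bar at the list's median; an asterisk marks a camera adjusted p under 0.05. Chemokines have the highest median (3.70) and cartilage matrix genes the lowest (-0.26).

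Of the 12 genes with the lowest log2 fold changes under the naming rule, Padi2, an enzyme that turns arginine in proteins into citrulline, fell most, from 8.87 ± 0.794 to 1.90 ± 0.188 CPM (log2 fold change -2.22, SE 0.14, edgeR adjusted p = 2.4e-12). The others were Lama3, Entpd3, Krt7, Trpm5, Gli1, Sfrp5, Msmp, Cldn19, Crb2, Sfrp4 and Zfp648, with log2 fold changes between -1.94 and -1.26. Lama3, at -1.94, stood at 0.375, 1.10 and 0.343 CPM in M-LPS-EV replicates 1, 2 and 3, so its size leans on replicate 2. Gli1, a transcription factor and target of hedgehog signalling, fell from 9.14 ± 0.612 to 3.08 ± 0.368 CPM, and the secreted Wnt inhibitors Sfrp5 and Sfrp4 from 11.98 ± 0.182 to 4.35 ± 0.510 CPM and from 4.18 ± 0.108 to 1.73 ± 0.366 CPM. On the TPM scale, where the added 1 shrinks sizes, Crb2 was no longer called (-0.31, limma adjusted p = 0.077).

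The share of a gene's transcripts could be compared for 8747 genes with at least 2 measured transcripts. In 77 of them the shares differed between the groups (edgeR diffSpliceDGE, Simes p with Benjamini-Hochberg adjustment), and 33 of these were also called for expression. The smallest adjusted p-values belonged to Prdx1, a peroxide-reducing enzyme, Slc38a10, Rpsa, a ribosomal protein, Larp4b, Lmnb2, which encodes lamin B2, and Dop1b. In Lmnb2 the transcript ENSMUST00000057623 made up 0% of the gene with M-EV and 17.3% ± 0.476 with M-LPS-EV (SD, n = 3; diffSpliceDGE adjusted p = 5.7e-06). In Prdx1, Slc38a10, Larp4b and Dop1b the transcript behind the call held under 5% of the gene in both groups. The counts of single transcripts are estimates, and in simulated data 48 genes with unchanged shares were among the calls. No weight is put on any 1 of these genes. With only transcripts of at least 10% of their gene's TPM 10 genes were called, and with transcripts of a mean count of at least 50 there were 14. Without M-EV replicate 3, or without M-LPS-EV replicate 2, the number of genes with changed transcript usage was 119.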

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

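The alternatives with a GC content and length offset, a minimum change of 1.2-fold and limma diffSplice on voom were chosen after seeing the data; all others were fixed before. Of 1351 values that the 80 called genes of the naming rule given in the text took under the alternatives, 1336 kept their direction and their call, 15 kept the direction only and 0 reversed. Genes named outside that rule, such as Il18 and Lbp, are not among the 80. These values leave out the size threshold of 1 on the log2 scale, which 53 of the 80 genes passed and 27 did not. Of 285 such values for the 19 called lists, 266 kept both and 19 the direction only. With fry 3 further lists were called, hypertrophy (adjusted p = 0.0012), fibroblast (0.014) and osteoblast markers (0.042). The number of genes with changed expression was 395 with a log2 fold change of at least 1, 2868 with the effective length offset, 2622 with limma-trend on log2(TPM + 1) and 1137 with the minimum change of 1.2-fold; the first and last are stricter by construction, and for the others the cause was not tested. Under RLE, upper-quartile, no count filter, a mean count of at least 50, DESeq2, limma-voom and the GC content and length offset it lay between 3796 and 4698, and between 3978 and 4317 when 1 library was left out. The called lists numbered 11 with an estimated correlation, for which the cause was not tested, 17 to 19 when 1 library was left out, and 17 to 22 in the other alternatives. The estimate was under the preset 0.01 for macrophage markers (-0.016), protease inhibitors (-0.043) and antiviral genes (0.0015). A higher correlation was thus not what ended their calls. For the other lists that lost their call it was above the preset, from 0.023 (matrix-degrading enzymes) to 0.15 (cytokines and growth factors). Whether the correlation ended those calls cannot be told, because p rose steeply also where the estimate was under the preset. For the cartilage list (estimate -0.013) the unadjusted camera p was 3.1e-12 with the preset and 0.0015 with the estimate. Genes called for transcript usage numbered 14 with a mean count of at least 50, where fewer transcripts were tested, and 10 with only transcripts of at least 10 percent of gene TPM. They numbered 104 with the gene-level F-test and 103 with limma diffSplice on voom (15 of them shared with the 77). When 1 library was left out there were 92 to 119, with 119 without M-EV replicate 3 and without M-LPS-EV replicate 2. No gene was called in all of these alternatives.

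Same-numbered libraries of the groups did not deviate together, with correlations of deviations across genes of 0.028, -0.044 and -0.019 for numbers 1, 2 and 3, and not every library correlated best with its own number. With the number as a replicate block 4519 genes with changed expression, 19 lists and 46 genes for usage were called.

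Among lists the side of 0 turned for uncalled ones: without a count filter for endothelial (adjusted p = 0.95) and skeletal muscle markers (0.93). With 1 library left out, list: skeletal muscle markers ranged from 0.59 to 0.99 and list: fibroblast markers from 0.77 to 0.95. The log2 fold change of Adamts4, not called, was -0.017 with the effective length offset and -0.0047 on the TPM scale, and ranged from -0.18 to 0.15 when 1 library was left out. Depth limits genes such as Casp1, Il1b and Tnf, whose counts were too few for a test.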

Other observations

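The tests of GC content or length bias, of a shared pool of chondrocytes, of macrophage RNA and of carried-over LPS, and the list of acute-phase plasma proteins, were chosen only after the result was seen. Genes named in this part that are outside the naming rule were chosen after their values were seen.

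More than 50% of the called genes differed by under 1.2-fold, which puts these small changes in question. Against GC content or length bias as the whole cause, an offset that removes each library's trend with both left 2407 calls under 1.2-fold, against 2358 without it, and 2137 of those 2358 genes were still called. The effective length offset and the TPM scale, given above, called fewer genes in all. Their calls under 1.2-fold were not counted, so an effect of effective length stays open. Open is that the libraries were drawn from a shared pool of chondrocytes: the Xist share of Xist plus Y-linked counts differed by only 2.08 percentage points over the 6 libraries, from 74.9% to 77.0%. A shared pool is a candidate explanation for the small spread between replicates, and it may make differences between preparations look reliable, whatever their size. No biological explanation of the small changes was tested.

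Of the tested NF-kB response and chemokine genes, 28 of 28 and 13 of 15 were called higher with M-LPS-EV. Against RNA of macrophages carried over with the vesicles as the whole cause, the 22 macrophage markers summed to 45.2 CPM in M-LPS-EV, 1.96% of the 2306 CPM by which the 54 genes of both lists rose in sum. Lcn2, from 48.3 to 1171 CPM, and Saa3, from 1.38 to 315 CPM, carry much of that rise. The sum thus does not speak for genes at a low level, such as Nos2 at 12.8 CPM with M-LPS-EV. Il1b and Tnf, which LPS raises in macrophages, stood at 0.135 and 0.280 CPM with M-LPS-EV. A selective loading of vesicles with a few transcripts was not tested. LPS carried over with the vesicles cannot be told apart from a vesicle effect, because the design holds 0 libraries of cells given LPS alone. A vesicle effect is the biological explanation the design names, and it stays open.

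Of 9 called genes with 0 counts in a group, 5 share at least 50% of their 31-base words with other genes (55.6%, against 7.33% of 300 other tested genes). Reads shared between near-identical genes are a candidate explanation for them. Summed over a gene and its copies, the counts of these 5 differed by a median of 1.28-fold between the groups. Whether reads only moved between copies cannot be told apart from a change of their sum, since that value lies between 1.2 and 1.5, the bounds set in advance. Saa1 and Saa2 share 46.8% and 44.5% of their words, while Acod1, with 0 and 48 counts, and Gm47204, with 127 and 0 counts, share none. No biological explanation was tested for these genes.

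Gli1 and Ihh, a hedgehog ligand with a log2 fold change of -1.23, were lower with M-LPS-EV, and lower hedgehog signalling may account for the fall of Gli1. The other targets Ptch1 (-0.17), Hhip (-0.99) and Pthlh (-0.88, edgeR adjusted p = 0.051) had a median log2 fold change of -0.88 (camera p = 0.0099 with the preset correlation and 0.060 with an estimated one). That median is the value of Pthlh, which was not called and had 65 and 33 counts in the M-EV and M-LPS-EV groups. Ptch1, the most abundant of these targets, fell little. For Sfrp4 and Sfrp5, lower expression of secreted Wnt inhibitors as a class was not borne out, since the 6 other tested members had a median of -0.036, with Wif1 (-0.40) and Frzb (-0.13) called lower. For the interferon-inducible GTPases, an interferon gamma response would raise MHC class II genes. Ciita, with 12 and 7 counts in the M-EV and M-LPS-EV groups, and H2-Aa, with 1 and 2, had too few counts for the test. The 4 tested had a median of -0.28, which the rule set in advance counted against the response. They went both ways, a spread that this rule left out, so the response is neither shown nor excluded. Among them H2-Ab1, the most abundant, rose by 1.51, while H2-Eb1 (-1.44) and H2-DMb1 (-0.35) fell and H2-DMa was not called.

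Of 17 acute-phase plasma proteins 6 could be tested and all of them rose, with a median log2 fold change of 5.77, or 5.26 with Saa1 and Saa2 at their bounds. The list was made after rises such as those of Saa2, Hp and Serpina3n were seen. Saa1 and Saa2, at 0 counts with M-EV, reached the test only through M-LPS-EV. The values thus describe these genes and do not test the class. Lbp, which presents LPS to its receptor, rose from 4.45 ± 0.483 to 167 ± 8.43 CPM, and Cp, which encodes ceruloplasmin, by 0.93 on the log2 scale. Hpx, the untested member with the most counts, had 28 and 26 counts in the M-EV and M-LPS-EV groups. Fga, Orm2 and Apcs had 0 counts in both groups.

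The 6 libraries can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split, the only 1 of the 10 with a result as large, gave 4614 genes with changed expression against a highest other value of 0, 19 lists against 13, and 77 genes for transcript usage against 62. Every other split also called lists, 7 to 13, and genes for transcript usage, 36 to 62. Each of them puts libraries of both groups on either side, so the difference between M-LPS-EV and M-EV adds to the spread within its sides. Part of that difference also stays between the sides. Whether the lists and usage genes called there stem from that part or are false calls cannot be told. The other values, the 0 called genes included, need not be what libraries without a group difference would give.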
